A study of Mus musculus with 8 samples.

How the data were processed

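Islets were isolated from the pancreas of female NOD/ShiLtJ mice by collagenase digestion and a density gradient, dispersed with Accutase, and sorted for live CD45+ cells, per the labels. Droplet libraries were made with the 10x Genomics 3' version 3 chemistry, which counts unique molecular identifiers (UMIs) near the 3' end of each RNA. The labels give 8 groups with 1 library each: untreated mice at 10 weeks of age, PBS given 2 times per week, and mIL-2/CD25 at 5 µg given 2 times or 1 time per week, to 15 weeks (5 weeks of treatment) or 30 weeks (20 weeks), and a group at 30 weeks that had 5 weeks of mIL-2/CD25 2 times per week and then PBS for 15 weeks, called off therapy here. Each library pooled 3 mice, so the mice within a library cannot be told apart. The labels give 3 library dates, and each date holds the libraries of 1 age.

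The deposited matrices hold UMI counts per gene and barcode for 32285 genes, with whole numbers and no normalization. Per the submitters' processing notes they were made with Cell Ranger 7.0.1 on mm10, while the file headers name Cell Ranger 7.1.0 for the 10-week and 30-week libraries and 7.0.1 for the 15-week libraries. Versions thus differed between ages and not within an age. The files hold 2571, 4674, 4004, 3629, 5999, 4973, 4232 and 6664 barcodes in the order the 10-week library, PBS at 15 weeks, 2/week at 15 weeks, 1/week at 15 weeks, PBS at 30 weeks, 2/week at 30 weeks, 1/week at 30 weeks and the off-therapy library, 36746 in all. No cell annotation by the authors was used here. Total UMIs were 24286880 in the 10-week library, 44097766 in PBS at 15 weeks, 36048936 in 2/week at 15 weeks, 37185359 in 1/week at 15 weeks, 48744092 in PBS at 30 weeks, 44544582 in 2/week at 30 weeks, 41189644 in 1/week at 30 weeks and 62824388 in the off-therapy library, and the median per retained cell was 7650.0, 7061, 7341, 7179, 6997, 6737, 7867 and 6851 in the same order. Gene positions were taken from the mm10 (GRCm38) annotation by gene identifier, and 135 of 135 named genes matched.

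Barcodes with under 300 detected genes or over 10% mitochondrial UMIs were left out (73, 145, 88, 105, 301, 205, 200 and 320 per library). Scrublet scores, as implemented in scanpy 1.11.5, were computed per library, and the barcodes with the highest scores were removed as doublets at 0.8% per 1000 barcodes (61, 184, 131, 121, 321, 202, 159 and 360). This left 2437, 4345, 3785, 3403, 5377, 4566, 3873 and 5984 cells, 33770 in all. Scrublet's automatic threshold, an alternative, marked 0.440%, 0.177%, 0.306%, 0.284%, 2.30%, 1.76%, 2.36% and 2.10%. It did not work in the 10-week and 15-week libraries, where it marked too few. Counts were scaled to each cell's total and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.0 gave 39 clusters in a first round on all cells and a further round on T and innate lymphoid cells. Clusters entered the further round when Cd3d, Cd3e, Cd3g, Ncr1 and Gata3 summed to at least 400 CPM, with Cd79a and Lyz2 each under 1000 CPM and under 5 markers of any class outside these lymphocytes.

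Clusters were called X-like from marker genes of 21 classes chosen before the data were examined. The scoring of the markers was set with the data at hand. A name needed at least 3 of its markers at 20 CPM or more with a log2 fold over the other cells of at least 0.5, and the class with most markers among the 10 genes of highest fold was taken, with the top 50 genes deciding between equals. T cell names also needed Cd3e and the fitting co-receptor, and Treg-like cells Foxp3. A cluster whose top 10 genes held more markers of another class than of its own stayed unnamed. Clusters were called mixed where 1 of 7 pairs of genes of unlike classes, formed from Cd3e, Cd79a, Lyz2, Foxp3, Ncr1 and Cd8b1, were each above 20% of the highest cluster's level. Cd3e with Ncr1 was not such a pair. Cluster T1, called gamma-delta T-like, held Cd3e at 652 CPM, Trdc at 890 and Ncr1 at 647, with Klra genes of NK cells among its leading genes, so its name is less secure. After the data had been seen, a marker was also required in at least 10% of a cluster's cells, and clusters led by genes of exocrine pancreas or stroma were kept unnamed. The exocrine-led cluster A20 made up 2.71%, 0.460%, 0.106%, 0.235%, 0.260%, 0.131%, 0.387% and 2.72% of the retained cells in the order above, and the stroma-led cluster A34 0.0821%, 0%, 0%, 0.0294%, 0%, 0.110%, 0.103% and 0.134%. Cluster T12, led by Il10, Lag3 and Il21, stayed unnamed because its leading genes held more markers of Treg than of CD4 Tconv cells. All unnamed clusters together held 8.17%, 5.64%, 4.52%, 5.02%, 3.74%, 7.51%, 4.93% and 5.83% of retained cells in that order, and mixed clusters 1.40%, 1.17%, 1.69%, 5.05%, 0%, 0%, 0.181% and 0.0334%.

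Shares of cells are given with exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and scaled to 1000000 UMIs per sum (CPM), and ratios of CPM carry exact conditional binomial 95% intervals. These intervals cover counting error only. Because each group has 1 library, no test across libraries was made, no p-value is given and no genes were counted as changed. Log2 ratios used a prior of 2 UMIs scaled to the depth. Where 1 library had 0 UMIs, the fold was computed against a floor of 3 counts and is a lower bound. A class was compared only with at least 50 cells in each library, which macrophage-like cells met only on therapy and off therapy at 30 weeks. Treated libraries were compared with PBS of the same age, the off-therapy library also with 2/week, and 2/week with 1/week. Both PBS libraries were set against the 10-week library as values only. For Foxp3 UMIs per droplet, all retained cells were thinned to 1500 UMIs, and those left with a Cd3d, Cd3e or Cd3g UMI and no Cd8a or Cd8b1 UMI were gated, so CD8 T cells that lost their Cd8 UMIs could enter. Shallower cells were left out (23, 37, 21, 25, 43, 78, 130 and 34), and B-like cells gave the background.

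The 17 gene lists and the rule for named genes were also fixed before the data were examined. Values of some genes that met the rule are not reported here. The lists were Treg identity and suppression, tissue effector Treg, IL-2 and STAT5 response, naive and central memory, cytotoxic effector, inhibitory receptors and exhaustion, anergy, T helper effector cytokines and receptors, interferon response, antigen presentation, B cell activation and germinal centre, inflammatory macrophage, tissue-resident and phagocytic macrophage, proliferation, tissue residency and recirculation, dissociation and stress, and free RNA from the pancreas. Several genes stand in more than 1 list. A list's value is the median log2 ratio over members with at least 20 UMIs in 1 of the 2 libraries, given for at least 5 members, beside the range of 95% of 10000 random lists of the same size matched on mean expression (1000 lists in the alternatives). Members with 0 UMIs in 1 library entered 26 of 404 medians. With them at the 3-count floor the largest shift was 2.06 log2, and 1 median changed sign (proliferation in CD8 T-like cells, off therapy against 2/week).

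Named genes were Foxp3, Il2ra, Ikzf2, Ctla4, Cd8a, Gzmk, Ifng and Pdcd1 in every comparison. Added to them were, per age, the genes with at least 50 UMIs in the class in 1 of the 3 libraries whose ratio to PBS had the same direction in both schedules with both intervals leaving out 1, ranked by the smaller absolute log2 ratio of the 2. The first 4 higher and 4 lower were taken in Treg-like, 3 and 3 in CD4 Tconv-like and CD8 T-like, and 2 and 2 in B-like cells. Off therapy the first 3 and 3 were taken per class, and for PBS against 10 weeks the first 5 and 5 over all cells. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor segment, predicted and free RNA genes were excluded, and the 2 highest and 2 lowest members with 50 UMIs served as examples of a list. For each gene the share of its UMIs in 1 cell was computed after the data had been seen.

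The median log2 ratio of all genes with 100 UMIs lay within 0.1 of 0 except in a few classes. It was 0.13 and 0.11 in NK-like and 0.17 and 0.18 in ILC2-like cells on 2/week and 1/week at 30 weeks, -0.18 and -0.14 in these classes off therapy against 2/week, and -0.12 and -0.12 in CD8 T-like cells of PBS mice at 15 and 30 weeks against 10 weeks. Scaling factors by trimmed means (TMM) were furthest from 0, among the classes with enough cells, at 0.15 log2 in B-like cells on 1/week at 30 weeks, -0.15 in NK-like cells off therapy against 2/week and -0.15 in CD8 T-like cells of PBS mice at 15 weeks against 10 weeks. The interval and list computations were tested on counts simulated from the class sums of 2/week and PBS at 15 weeks. Intervals left out 1 in the right direction for 83.6%, 97.0%, 86.6% and 98.5% of genes changed 1.5-fold among the 5980, 8141, 7128 and 8122 genes of Treg-like, CD4 Tconv-like, CD8 T-like and B-like sums, for 90.9%, 98.5%, 97.0% and 98.5% of those changed 2-fold, and for 100.0% of those changed 4-fold in each class. They also left out 1 for 4.48%, 4.42%, 3.94% and 4.41% of unchanged genes. The simulated counts were independent Poisson draws, so these rates do not cover genes whose UMIs gather in few cells.

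Alternatives chosen before the data were examined were doublets kept, the Scrublet automatic threshold, a stricter cell filter (at least 800 genes, at most 5% mitochondrial UMIs), resolutions of 0.6 and 1.5, log values centred per library date, Treg markers and IL-2 response genes left out of the variable genes, a gate per droplet, no thinning or thinning to 1000 UMIs, priors of 0.5 and 5 UMIs, TMM scaling, a total without immunoglobulin, haemoglobin, mitochondrial and pancreas genes, list members with at least 100 UMIs, all deposited barcodes, and a mean over cells of each cell's own CPM. Added after the data had been seen were the omission of each gene's top cell in each library, the counting of cluster T12 as CD4 Tconv-like and a droplet gate set on full counts before thinning. Computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.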

Results

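Immune cells from the pancreatic islets of female NOD mice, an inbred strain that develops autoimmune diabetes spontaneously, were profiled by droplet single-cell RNA sequencing after sorting of live CD45+ cells. The treatment was mIL-2/CD25, a fusion protein of mouse interleukin-2 and CD25, the alpha chain of its receptor, given at 5 µg per injection. The 8 libraries were 1 untreated library at 10 weeks of age, 3 at 15 weeks (PBS, 2 injections per week and 1 injection per week) and 4 at 30 weeks (PBS, 2/week, 1/week, and 2/week for 5 weeks followed by 15 weeks off therapy). Each library pooled the islets of 3 mice. Total UMIs ranged from 24286880 in the 10-week library to 62824388 in the off-therapy library, and 2437 to 5984 cells per library were retained, with a median of 6737 to 7867 UMIs. Each group has 1 library, so no difference has a replicate check and none was tested. Brackets give exact 95% intervals that cover counting error only. Libraries of each age were made on 1 date, so age and library date cannot be told apart, and treated mice are compared with PBS mice of the same age.

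The first question was whether 5 weeks of mIL-2/CD25 altered which lymphocytes occupied the islets at 15 weeks. Regulatory T (Treg)-like cells, the Foxp3+ cells that restrain autoreactive T cells, made up 40.6% (37.8 to 43.5%) of Treg-like and conventional CD4 T (Tconv)-like cells on 2/week and 21.3% (18.2 to 24.7%) on 1/week, against 13.5% (11.5 to 15.7%) in PBS mice. CD8 T-like cells, which include the cells that kill beta cells, were 15.7% (13.8 to 17.7%) of the Treg-like, CD4 Tconv-like and CD8 T-like cells on 2/week, 33.2% (30.2 to 36.3%) on 1/week and 43.6% (41.4 to 45.9%) in PBS mice. There were 2.19 Treg-like cells per CD8 T-like cell on 2/week, 0.429 on 1/week and 0.174 in PBS mice. The ratios to PBS were 12.6 (9.91 to 16.0) and 2.46 (1.88 to 3.22). As a share of all retained cells, Treg-like cells were 3.89 (3.22 to 4.72) times PBS on 2/week and 1.21 (0.946 to 1.54) on 1/week, and CD4 Tconv-like cells 0.885 (0.801 to 0.977) and 0.693 (0.620 to 0.774). Group 2 innate lymphoid (ILC2)-like cells, tissue-dwelling producers of type 2 cytokines, were 12.5% of retained cells on 2/week and 6.52% on 1/week against 1.86% in PBS mice, ratios of 6.69 (5.27 to 8.58) and 3.50 (2.70 to 4.57). Natural killer (NK)-like cells were 1.97 (1.70 to 2.28) and 1.86 (1.60 to 2.17) times the PBS share, with cluster T6 at 6.73 (5.10 to 9.03) and 1.99 (1.42 to 2.81) and cluster T5 at 0.722 (0.582 to 0.893) and 1.83 (1.54 to 2.18) times. The B-like share was 0.705 (0.640 to 0.776) times that of PBS mice on 2/week and 1.10 (1.01 to 1.20) times on 1/week. Cells in the clusters named for cell cycle genes were 0.766% of retained cells on 2/week, 3.29% on 1/week and 4.72% in PBS mice. Of these clusters, A16 carried Cd3e at 579 CPM and Cd8b1 at 178, and held 13, 74 and 166 cells in that order. It stayed outside the T cell classes, so their shares and proliferation lists leave out its cells.

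**Figure D1:**
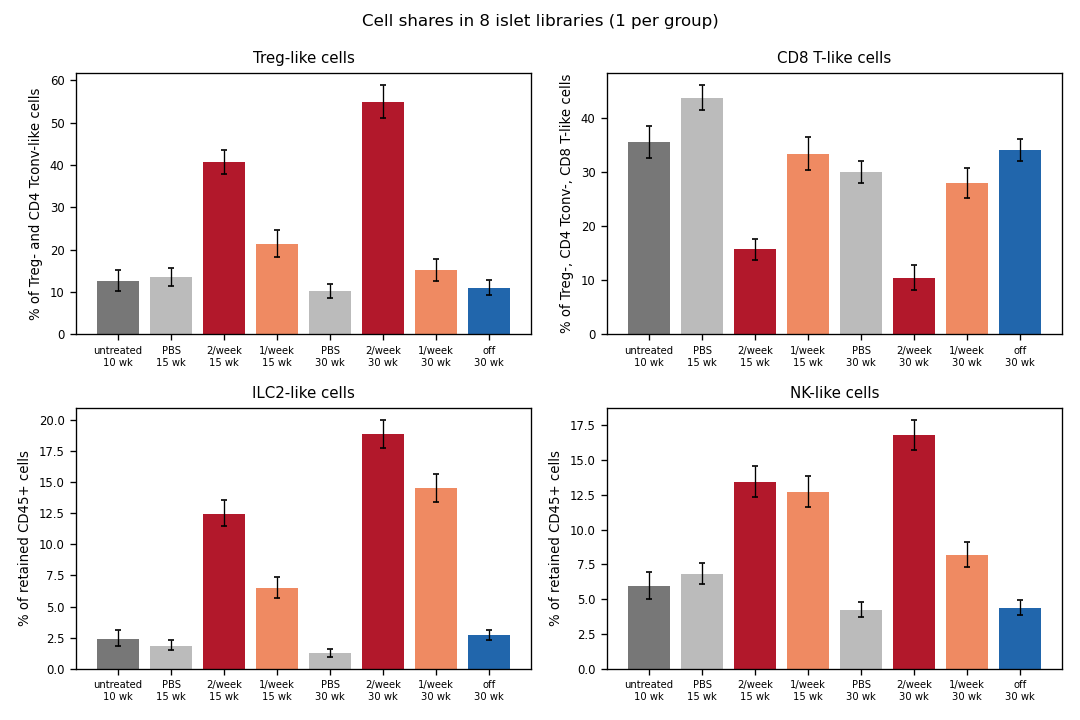
Shares of cells in percent (vertical axes, starting at 0) in each of the 8 libraries, for Treg-like cells among Treg-like and CD4 Tconv-like cells, CD8 T-like cells among Treg-like, CD4 Tconv-like and CD8 T-like cells, and ILC2-like and NK-like cells among retained cells, with bars of exact 95% binomial intervals for counting error only. On 2/week the Treg-like share stood at 40.6% at 15 weeks and 54.9% at 30 weeks, against 13.5% and 10.1% in PBS mice, and it was 11.0% in the off-therapy library.

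Within Treg-like cells at 15 weeks, Foxp3 itself was nearly level, at 264 CPM on 2/week, 263 on 1/week and 242 in PBS mice (ratios 1.09 (0.951 to 1.25) and 1.09 (0.911 to 1.29)). Il2ra, which encodes CD25, was 2.97 (2.54 to 3.51) times its PBS level on 2/week and 2.09 (1.73 to 2.54) times on 1/week. Gzmb, the cytotoxic granule protease granzyme B, was 7.59 (4.69 to 13.1) and 6.68 (3.98 to 11.9) times the PBS level. Lipa, the lysosomal acid lipase, stood at 0.378 (0.278 to 0.515) and 0.353 (0.213 to 0.565) of PBS, and Ppa1 at 0.420 (0.301 to 0.589) and 0.362 (0.207 to 0.608). Lower as well were Rapgef5 at 0.454 (0.320 to 0.648) and 0.429 (0.246 to 0.722), and Irak1bp1 at 0.430 (0.292 to 0.639) and 0.441 (0.240 to 0.777). Ikzf2, which encodes the Treg transcription factor Helios, was at 1.19 (1.14 to 1.25) and 1.24 (1.17 to 1.31), and Ctla4 at 0.958 (0.911 to 1.01) and 1.09 (1.03 to 1.16). With finer clustering the direction of Ctla4 on 1/week turned (log2 -0.03). Pard3b (at least 5.35-fold and at least 5.15-fold higher, with 0 PBS UMIs) and Dach2 also met the rule for named genes, but 1 cell held 71.4% of the Pard3b UMIs on 1/week and 83.1% and 100.0% of those of Dach2 on 2/week and 1/week. Without each gene's top cell, Dach2 was at log2 1.08 and -0.57. With finer clustering the log2 ratios were smaller for Gzmb (1.77 and 1.16 against 2.86 and 2.60), for Pard3b (1.75 and 1.22 against 4.30 and 3.06) and for Lipa on 1/week (-0.80 against -1.43). With doublets kept, Irak1bp1 on 1/week was at -0.47 against -1.10.

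Genes of the IL-2 and STAT5 response were mostly higher in Treg-like cells at 15 weeks: 18 of 22 measured members on 2/week (median log2 ratio 0.31, random lists -0.18 to 0.26) and 16 of 21 on 1/week (median 0.20, random lists -0.12 to 0.20). Gzmb (2.86) and Socs2, a feedback inhibitor of cytokine signalling (2.62), led on 2/week, and Jak3 (-0.49) and Stat5a (-0.15) were lowest. The Treg identity and suppression list had 23 of 23 members higher on 1/week (median 0.33, random lists -0.11 to 0.19) and 15 of 24 on 2/week (median 0.14, random lists -0.18 to 0.24). On 2/week Gzmb and Lrrc32, which encodes the carrier GARP of latent TGF-beta (2.02), were highest in that list and Lag3 (-1.12) and Itgae (-0.95) lowest. At the finer clustering these medians were 0.43 on 2/week and 0.09 on 1/week. Tissue effector Treg genes had a median of -0.35 on 2/week (random lists -0.19 to 0.23), with Klrg1 (3.16) and Pparg (1.56) highest and the chemokine receptors Cxcr6 (-1.87) and Cxcr3 (-1.22) lowest. On 1/week the median of that list was 0.20. Pparg is also a leading gene of the ILC2-like cluster T8, and RNA from such cells in its value was not told apart. Interferon response genes were lower in 22 of 25 members on 2/week (median -0.45, random lists -0.21 to 0.21), with Ly6a (-1.69) and Isg15 (-1.43) lowest, and the median on 1/week was -0.11. Genes of dissociation and stress were higher in the same library, with a median of 0.64 on 2/week (random lists -0.16 to 0.29) led by Atf3 (2.42) and Hspa1a (1.90), and 0.08 on 1/week. The anergy list had a median of 0.40 on 2/week (random lists -0.23 to 0.34), led by Rnf128 (1.68) and Nt5e (1.22), and 0.18 on 1/week.

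In CD4 Tconv-like cells at 15 weeks, genes of helper and killer function were lower on 2/week, and genes of naive and central memory cells were higher. All measured members of the T helper effector list were lower (18 of 18, median log2 ratio -0.59, random lists -0.19 to 0.11), as were 19 of 21 cytotoxic effector genes (median -0.79, random lists -0.20 to 0.10) and 15 of 15 proliferation genes (median -0.79, random lists -0.28 to 0.16). Il2 (-3.23), Gzma (-3.62), Ccl3 (-3.47) and Top2a (-0.97) were among the lowest. The proliferation values do not cover the dividing cells of cluster A16. Ifng, the cytokine of type 1 helper cells, was 0.426 (0.376 to 0.481) of its PBS level on 2/week and 0.695 (0.618 to 0.781) on 1/week. Over all cells Cd8b1 stood at 26.2 CPM on 2/week and 104 in PBS mice, so RNA from CD8 T cells in the cytotoxic values was not told apart. Naive and central memory genes were higher in 12 of 17 members on 2/week (median 0.54) and 15 of 17 on 1/week (median 0.45), led on 2/week by Igfbp4 (1.60) and Dapl1 (1.04). Inhibitory receptor and exhaustion genes were lower in 17 of 19 members on 2/week (median -0.42), with Tigit (-1.24) and Nrn1 (-1.09) lowest, and had a median of 0.05 on 1/week. In the interferon response list 29 of 30 members were lower on 2/week (median -0.61) and 29 of 30 on 1/week (median -0.24), beside stress medians of -0.01 and -0.26. Antigen presentation genes had a median of -0.38 on 2/week (random lists -0.22 to 0.12), with the class II genes H2-Aa (-1.07) and H2-Ab1 (-0.72) lowest. B-like cells were 18.0% of retained cells on 2/week and 25.6% in PBS mice, and RNA from such cells in these sums was not told apart. Genes of free pancreas RNA, which mark other cell types, had medians of -1.35 and -1.43. Cluster T0, led by Lef1 and Igfbp4 with Ccr7, held 505 of the 707 cells of the class on 2/week and 386 of 917 in PBS mice, where cluster T2, led by Esm1 and Cd40lg, held 368 against 118 on 2/week and T11 155 against 74. The class values thus also follow the mix of the clusters.

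Named by the fixed rule in CD4 Tconv-like cells at 15 weeks was Ncr1, an NK receptor gene, at 6.76 (3.15 to 16.6) and 18.0 (8.70 to 43.1) times PBS on 2/week and 1/week. NK-like cells were 13.4% and 12.7% of retained cells on these schedules and 6.81% in PBS mice. RNA from NK cells, free or in doublets, was thus not told apart from RNA of the CD4 Tconv-like cells. Under the stricter cell filter the log2 ratio of Ncr1 was 0.26 and 1.67 against 2.46 and 3.79. For Ifitm1, 1 cell held 66.7% of the UMIs on 2/week. Cxcl2, Csf2 and Ccl1 were lower on both schedules, but 1 PBS cell held 82.3%, 92.7% and 97.0% of their PBS UMIs, and without each gene's top cell Csf2 and Ccl1 were higher than in PBS (log2 0.63 and 0.56 on 2/week).

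CD8 T-like cells at 15 weeks carried less effector RNA on 2/week. Gzmk, a granzyme of memory and exhausted CD8 T cells, was 0.453 (0.385 to 0.531) of its PBS level on 2/week and 0.795 (0.712 to 0.886) on 1/week, and Ifng 0.619 (0.556 to 0.688) and 0.928 (0.857 to 1.00). Pdcd1, which encodes the inhibitory receptor PD-1, was at 0.659 (0.556 to 0.777) and 0.968 (0.854 to 1.09), while Cd8a was at 0.971 (0.899 to 1.05) and 0.951 (0.889 to 1.02). Cytotoxic effector genes were lower in 23 of 24 members on 2/week (median log2 ratio -0.70, random lists -0.17 to 0.10), with Gzmb (-2.43) and Ccl3 (-1.88) lowest, and had a median of -0.01 on 1/week. Inhibitory receptor and exhaustion genes were lower in 18 of 20 members (median -0.59), with Havcr2, which encodes TIM-3 (-1.65), and Cd38 (-1.20) lowest. Proliferation genes were lower in 14 of 16 (median -0.97), with Stmn1 at -1.45. These values leave out the dividing cells of cluster A16, which held Cd8b1 but stayed outside the class. The stricter cell filter put the exhaustion median at -0.97, and with at least 100 UMIs per member the proliferation median was -0.35. Naive and central memory genes were higher in 16 of 17 members (median 0.75), led by Igfbp4 (2.09) and Dapl1 (1.15). In the interferon response list 25 of 29 members were lower on 2/week (median -0.26, or -0.41 without each gene's top cell) and 27 of 29 on 1/week (median -0.41), beside stress medians of 0.07 and -0.20. Tissue residency genes had medians of 0.21 and 0.18. Itgae, the integrin chain CD103 that binds E-cadherin, was 2.92 (2.28 to 3.71) and 2.41 (1.91 to 3.04) times PBS. Tnfsf11, which encodes RANKL, was at 7.91 (5.47 to 11.6) and 3.07 (2.01 to 4.70), and Cd40lg 0.256 (0.108 to 0.521) and 0.362 (0.20 to 0.613). Tnfrsf4, at 3.35 (2.37 to 4.71) times PBS on 2/week, was lower under the stricter cell filter (log2 -0.32), where Tnfsf11 was at 2.10 against 2.90, and 1 PBS cell held 97.0% of the Spp1 and 75.0% of the Areg UMIs. The largest cluster of the class was T4, led by Cd8a, Gzmk and Havcr2, in PBS mice (441 of 821 cells) and on 1/week (179 of 315), and T10, led by Dapl1, on 2/week (92 of 221).

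In B-like cells at 15 weeks Ly6a, an interferon-inducible surface antigen gene, was 0.138 (0.111 to 0.170) of its PBS level on 2/week and 0.458 (0.409 to 0.513) on 1/week. Nectin2, an adhesion molecule gene, was 13.8 (5.96 to 39.1) and 5.93 (2.45 to 17.3) times PBS. Tppp3, a tubulin-binding protein gene with 0 UMIs in PBS B-like cells, was at least 8.70-fold and at least 21.9-fold higher. For Nrgn, lower at 0.443 (0.262 to 0.723) and 0.239 (0.130 to 0.416), 1 cell held 77.3% of the UMIs on 2/week. Of the interferon response genes 24 of 25 were lower on 2/week (median log2 ratio -0.68, random lists -0.09 to 0.13) and 24 of 26 on 1/week (median -0.38), beside stress medians of 0.15 and -0.20. In the B cell activation and germinal centre list Zbtb32 (1.97) and Cd80 (1.48) were highest and Apoe (-0.97) lowest on 2/week, and the medians were 0.04 and 0.12. Antigen presentation medians were -0.05 and -0.02.

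At 30 weeks, after 20 weeks of treatment, the 2/week library again held more Treg-like and fewer CD8 T-like cells than PBS mice. Treg-like cells were 54.9% (51.1 to 58.8%) of Treg-like and CD4 Tconv-like cells on 2/week, 15.1% (12.7 to 17.9%) on 1/week and 10.1% (8.61 to 11.8%) in PBS mice. CD8 T-like cells were 10.4% (8.26 to 12.8%), 27.9% (25.2 to 30.7%) and 29.9% (27.9 to 31.9%) of the Treg-like, CD4 Tconv-like and CD8 T-like cells. Treg-like cells per CD8 T-like cell stood at 4.75 on 2/week, 0.391 on 1/week and 0.237 in PBS mice. Both T cell classes were smaller shares of all retained cells on 2/week, at 0.142 (0.111 to 0.181) times PBS for CD8 T-like and 0.263 (0.231 to 0.298) for CD4 Tconv-like cells, while Treg-like cells were at 2.85 (2.35 to 3.48) times. On 1/week Treg-like cells were at 1.09 (0.848 to 1.40) and CD4 Tconv-like cells at 0.687 (0.625 to 0.755) times the PBS share of retained cells. ILC2-like cells reached 18.8% (17.7 to 20.0%) of retained cells on 2/week and 14.5% (13.4 to 15.7%) on 1/week against 1.23% (0.951 to 1.56%) in PBS mice, ratios of 15.3 (11.9 to 20.0) and 11.8 (9.16 to 15.5). NK-like cells were 3.97 (3.42 to 4.62) and 1.94 (1.63 to 2.31) times the PBS share, of which cluster T6, led by Ccdc80 and Klrb1b, was at 16.0 (11.8 to 22.4) and T5, led by Gzma, at 0.809 (0.630 to 1.04) times PBS on 2/week, and at 5.04 (3.57 to 7.23) and 1.13 (0.894 to 1.43) on 1/week. B-like cells were at 0.495 (0.458 to 0.534) and 0.553 (0.511 to 0.598) times. Type 1 conventional dendritic cell (cDC1)-like cells, of the type that cross-presents antigen, were 7.46 (3.67 to 17.1) and 10.3 (5.13 to 23.6) times the PBS share, and cells like antibody-secreting plasma cells 5.93 (3.96 to 9.16) and 2.01 (1.22 to 3.35) times. The Treg share was also counted per droplet, as cells with a Foxp3 UMI among those with Cd3 RNA and without Cd8 RNA. Without thinning, its ratio to PBS was 1.85 (1.49 to 2.32) on 2/week and 0.867 (0.654 to 1.14) on 1/week. Thinned to 1500 UMIs, the ratios were 2.20 (1.58 to 3.10) and 1.01 (0.660 to 1.53). The gate without thinning also took in NK-like, ILC2-like, gamma-delta T-like and unnamed cells. These were 64.6% of it on 2/week, 49.6% on 1/week and 27.4% in PBS mice.

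Treg-like cells at 30 weeks carried Foxp3 at 261 CPM on 2/week, 299 on 1/week and 287 in PBS mice, ratios of 0.909 (0.784 to 1.06) and 1.04 (0.869 to 1.25). Il2ra was 3.44 (2.88 to 4.12) and 2.87 (2.35 to 3.53) times PBS, Ikzf2 1.07 (1.02 to 1.12) and 1.07 (1.01 to 1.13), and Ctla4, the inhibitory receptor that Treg cells use against costimulation, 0.646 (0.610 to 0.685) and 0.845 (0.788 to 0.907). Lower than in PBS mice were Cxcr6, a chemokine receptor gene of tissue effector T cells, at 0.133 (0.0840 to 0.203) and 0.140 (0.0677 to 0.260). So were the cytotoxic granule gene Nkg7 at 0.109 (0.0773 to 0.150) and 0.273 (0.192 to 0.381), and Tmem140 at 0.280 (0.171 to 0.450) and 0.181 (0.0694 to 0.401). Over all cells Cd8b1 was at 6.25 CPM on 2/week, 25.5 on 1/week and 53.3 in PBS mice. RNA from CD8 T cells in the Nkg7 values was thus not told apart from RNA of the Treg-like cells. Actr3b, an actin nucleation gene, and Fsd1l had 0 UMIs in PBS Treg-like cells and were at least 13.3-fold and at least 5.28-fold, and at least 8.37-fold and at least 3.08-fold higher. Zdhhc14, a palmitoyltransferase gene with 1 PBS UMI, was 25.1 (4.31 to 1011) and 26.4 (4.23 to 1095) times PBS. Auts2 and Dgki also met the rule, with 56.7% of the Auts2 UMIs on 1/week and 70.0% of the Dgki UMIs on 2/week in 1 cell. With finer clustering the log2 ratio on 1/week was -0.99 for Cxcr6 (against -2.66), -0.68 for Nkg7 (against -1.83) and 2.13 for Zdhhc14 (against 3.13).

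The Treg identity and suppression list was split at 30 weeks, with 15 of 24 members lower on 2/week (median log2 ratio -0.30, random lists -0.26 to 0.28) and 14 of 23 on 1/week (median -0.19). Lrrc32 (1.82) and Il2ra (1.77) were highest on 2/week, and Lag3 (-2.76) and Itgae (-2.46) lowest. The IL-2 and STAT5 response had medians of 0.07 and 0.06, with Socs2 (2.97) and Myc (2.19) highest and Tnfrsf4 (-0.79) lowest on 2/week. Tissue effector Treg genes were lower in 17 of 24 members on 2/week (median -0.59), where Pparg (2.84) and the IL-33 receptor gene Il1rl1 (2.26) were higher and Cxcr3 (-3.17) and Cxcr6 lower. Over all cells Il1rl1 was at 179 CPM on 2/week and 17.2 in PBS mice, and Pparg is a leading gene of the ILC2-like cluster T8. RNA from ILC2-like cells in the values of Pparg and Il1rl1 was thus not told apart. Cytotoxic effector genes were lower in 13 of 17 members on 2/week (median -0.60) and 11 of 13 on 1/week (median -1.19). The 1/week median was -0.23 with finer clustering. RNA from CD8 T cells in these sums was not told apart from RNA of the Treg-like cells. Interferon response genes were lower in 23 of 25 members on 2/week (median -1.0, random lists -0.29 to 0.25), with Ly6a at -3.41 and Zbp1 at -1.48, and had a median of -0.09 on 1/week. Stress genes had medians of 0.52 and 0.34 in the same cells, led by Atf3 (2.08).

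CD4 Tconv-like cells on 2/week at 30 weeks had lower cytotoxic RNA than PBS cells. Gzmk was 0.0538 (0.0146 to 0.139) of PBS on 2/week and 0.180 (0.122 to 0.258) on 1/week. Ccl4, a chemokine gene of activated effector cells, was at 0.174 (0.113 to 0.257) and 0.135 (0.0995 to 0.181), and Ifng 0.265 (0.204 to 0.338) and 0.332 (0.285 to 0.384). Under the stricter cell filter the 1/week log2 ratio was -0.37 for Ccl4 (against -2.85) and -1.70 for Gzmk (against -2.42). Scin, an actin-severing protein gene, had 0 UMIs on 2/week against 71 in PBS cells, at least 5.14-fold lower, and was 0.184 (0.0714 to 0.399) of PBS on 1/week. That bound did not hold under the stricter filter or with finer clustering, where the 2/week log2 ratio was -1.23 and -1.25. Il2ra was 8.61 (6.99 to 10.7) and 8.58 (7.14 to 10.4) times PBS. Ccr3, Il13 and Il5, genes of type 2 immunity, ranked highest by the fixed rule. Ccr3 and Il5 are leading genes of cluster T21, which held 31 cells on 2/week, 113 on 1/week and 1 in PBS mice. They are thus not a result apart from that cluster. Il13 is a leading gene of the ILC2-like cluster T8, and RNA from such cells in these sums was not told apart. Il2ra stood at 691 CPM in T21, against 2.94 in T0, the largest cluster of the class in every library. T0 held 193 of 296 cells on 2/week and 582 of 1326 in PBS mice, T2 53 against 547 and T11 11 against 163, so the class values also follow this mix. Over all cells of that library Cd8b1 was 0.117 (0.103 to 0.133) and Gzmk 0.0388 (0.0312 to 0.0478) of PBS, so RNA from CD8 T cells in these sums was not told apart from RNA of the cells themselves. Cytotoxic effector genes were lower in 15 of 22 members on 2/week (median log2 ratio -0.76, random lists -0.22 to 0.19) and had a median of -0.57 on 1/week, with Gzmk (-3.99) and Ccl5 (-3.19) lowest on 2/week. Naive and central memory genes were higher in 13 of 17 members on 2/week (median 0.42), led by Actn1 (0.88) and Bach2 (0.79). Inhibitory receptor genes had a median of -0.78 on 2/week, with Rgs16 (-1.80) and Tigit (-1.75) lowest, and -0.16 on 1/week, which became 0.26 under the stricter cell filter. Of the interferon response genes 28 of 30 were lower on 2/week (median -0.61) and 16 of 30 on 1/week (median -0.05), beside stress medians of 0.23 and 0.15.

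CD8 T-like cells at 30 weeks numbered 76 on 2/week, 299 on 1/week and 629 in PBS mice. Gzmk was 0.224 (0.155 to 0.315) of PBS on 2/week and 0.370 (0.323 to 0.421) on 1/week, and Gzmb 0.264 (0.135 to 0.466) and 0.262 (0.195 to 0.345). Klrg1, a receptor gene of terminal effector cells, was at 0.229 (0.0465 to 0.686) and 0.235 (0.127 to 0.404). Ifng was 0.818 (0.675 to 0.984) and 0.674 (0.607 to 0.748) of PBS, and Pdcd1 was higher, at 1.58 (1.16 to 2.12) and 1.39 (1.16 to 1.66) times, with Cd8a at 0.995 (0.874 to 1.13) and 0.972 (0.908 to 1.04). Klri2, an NK receptor gene, was 6.91 (4.67 to 10.2) and 3.37 (2.47 to 4.66) times PBS, Zgrf1 3.37 (1.88 to 5.84) and 3.61 (2.54 to 5.19), and Jhy 4.35 (1.49 to 11.5) and 7.91 (4.38 to 15.3). Ptprk had 0 UMIs on 2/week against 62 in PBS cells, at least 2.37-fold lower (log2 -1.08 under the stricter cell filter), but was level on 1/week under the stricter cell filter (log2 -0.01 against -1.54), where Jhy on 1/week was at 1.27 against 2.77. Cytotoxic effector genes were lower in 20 of 24 members on 2/week (median log2 ratio -0.68, random lists -0.21 to 0.24) and 17 of 24 on 1/week (median -0.44). Inhibitory receptor and exhaustion genes were lower in 16 of 20 on 2/week (median -0.81, or -1.26 without each gene's top cell), with Tox2 (-3.92) near the foot of the list, and had a median of -0.04 on 1/week. Naive and central memory genes were higher in 16 of 17 on 2/week (median 0.64), led by Igfbp4 (1.32) and Actn1 (1.24). Interferon response genes were lower in 27 of 28 members on 2/week (median -0.69, or -0.63 with members at 0 UMIs set to the 3-count floor), beside a stress median of 0.23. Cluster T10 held 41 of the 76 cells on 2/week and 124 of 299 on 1/week, while T9, led by Gzmk, and T4 held 235 and 229 of the 629 PBS cells.

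B-like cells at 30 weeks carried 49.0 CPM of the heat shock gene Hspa1a on 2/week, 28.4 on 1/week and 254 in PBS mice, ratios of 0.193 (0.174 to 0.214) and 0.112 (0.0976 to 0.128). Tppp3 was again at 0 UMIs in PBS cells and at least 111-fold and at least 237-fold higher on therapy, and its relative Tppp was 54.3 (14.3 to 459) and 58.8 (15.6 to 497) times PBS. B cell activation and germinal centre genes were higher in 16 of 24 members on 2/week (median log2 ratio 0.30, random lists -0.09 to 0.25) and 19 of 22 on 1/week (median 0.31), led on 2/week by Zbtb32 (3.67) and the costimulatory ligand gene Cd80 (2.69). Antigen presentation genes were lower in 17 of 21 on 2/week (median -0.30), with H2-Oa (-0.74) and H2-K1 (-0.64) lowest. Interferon response genes were lower in 22 of 25 members on 2/week (median -0.57), with Ly6a (-2.84) lowest, and had a median of -0.24 on 1/week. Stress genes, of which Hspa1a is a member, were lower too, with medians of -0.41 and -0.48. In B-like cells off therapy the stress median was below PBS as well. An effect of treatment on these genes was thus not told apart from a PBS library high in them. For Ifitm1, lower on both schedules, 1 PBS cell held 86.0% of the UMIs. Cluster A0 held 1379 of the 2207 PBS B-like cells, and cluster A1, led by Bank1 and Cr2, held 548 of 927 on 2/week and 648 of 879 on 1/week. Cluster A13, led by Agbl1, Sox5 and Fcrl5, held 89 of the PBS cells, 239 of those on 2/week and 151 of those on 1/week. The class values thus also follow the mix of the clusters.

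**Figure D2:**
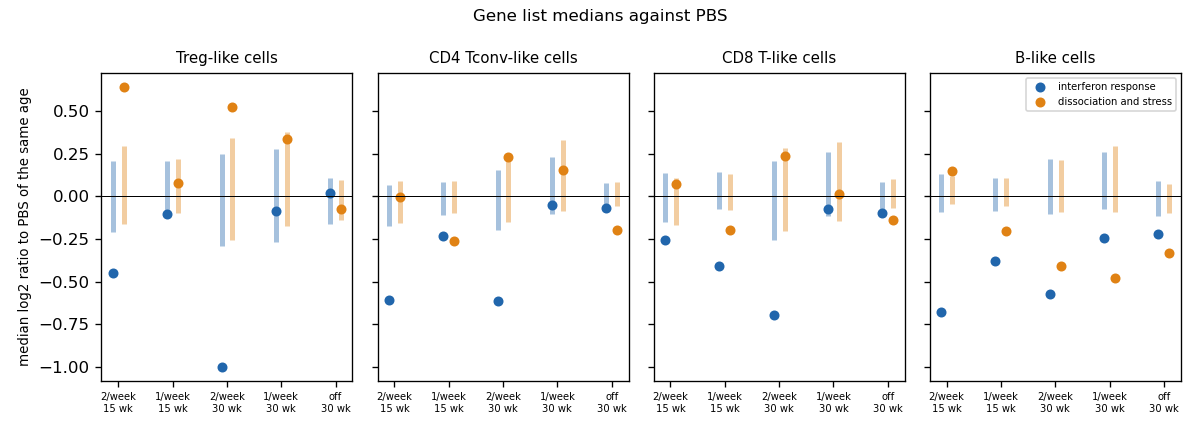
Median log2 ratio to PBS of the same age (vertical axis) for the interferon response list (blue) and the dissociation and stress list (orange) in Treg-like, CD4 Tconv-like, CD8 T-like and B-like cells, for 2/week and 1/week at 15 weeks and 2/week, 1/week and off therapy at 30 weeks, with pale bars for the range of 95% of 10000 random lists. On 2/week the interferon medians at 30 weeks were -1.0, -0.61, -0.69 and -0.57, while the stress medians were 0.52, 0.23, 0.23 and -0.41.

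The off-therapy library addressed what remained 15 weeks after 5 weeks of 2/week. Treg-like cells were 11.0% (9.38 to 12.7%) of Treg-like and CD4 Tconv-like cells, 1.09 (0.862 to 1.37) times the PBS share and 0.20 (0.164 to 0.242) times that on sustained 2/week. CD8 T-like cells were 34.0% (32.0 to 36.1%) of the Treg-like, CD4 Tconv-like and CD8 T-like cells, 1.14 (1.02 to 1.27) times PBS and 3.28 (2.59 to 4.21) times 2/week. NK-like cells were 1.04 (0.865 to 1.24) times PBS and 0.261 (0.226 to 0.301) times 2/week. ILC2-like cells were 2.67% of retained cells, 2.18 (1.63 to 2.95) times PBS and 0.142 (0.119 to 0.168) times 2/week. cDC1-like cells were 8.09 (4.06 to 18.3) times PBS, plasma cell-like cells 3.25 (2.14 to 5.09) times, and gamma-delta T-like cells 0.675 (0.570 to 0.799) times. Of the gamma-delta T-like cells, cluster T1, whose name is less secure, held 197 off therapy and 285 in PBS mice. Cluster T13, led by Cd163l1, held 51 and 45, so the lower class share lay in T1. Counted per droplet by Foxp3 UMIs, the Treg share relative to 2/week was 0.483 without thinning and 0.363 thinned to 1500 UMIs.

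In Treg-like cells off therapy, Foxp3 was 0.664 (0.544 to 0.809) of PBS and 0.731 (0.608 to 0.874) of 2/week, and Il2ra 0.708 (0.537 to 0.930) and 0.206 (0.164 to 0.257). Lipa was 2.64 (1.66 to 4.32) times PBS, while Gadd45g, a growth arrest gene, was at 0.202 (0.0919 to 0.399) and Ccl4 at 0.225 (0.142 to 0.344). Penk, Dscam and Dgki also met the rule, with 80.3% and 42.6% of the off-therapy UMIs of Penk and Dscam, and 50.7% of the PBS UMIs of Dgki, in 1 cell. With doublets kept the log2 ratio of Gadd45g was -1.35 against -2.12. Relative to 2/week, Ly6a was 19.3 (14.7 to 25.7) times and Cxcr3, a chemokine receptor gene of type 1 cells, 8.54 (6.06 to 12.3) times. Pparg, a transcription factor gene of tissue Treg cells, was 0.0263 (0.000658 to 0.150) of 2/week with 1 UMI. It is also a leading gene of the ILC2-like cluster T8, and RNA from such cells on 2/week was not told apart. Myt1l and Lypd1 had 0 UMIs, at least 7.56-fold lower and at least 7.41-fold lower, the latter with a log2 ratio of only -1.97 with doublets kept. The Treg identity and suppression list was lower than PBS in 20 of 23 members (median log2 ratio -0.45, random lists -0.15 to 0.09, and -0.25 with doublets kept), with Lag3 (-1.83) and Il10 (-1.56) lowest. The IL-2 and STAT5 list had a median of -0.19 against PBS (-0.33 with at least 100 UMIs per member) and -0.30 against 2/week, where Socs2 (-2.32) was lowest. Interferon response genes had a median of 0.02 against PBS and were higher than on 2/week in 24 of 24 members (median 1.08), beside stress medians of -0.07 and -0.60.

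CD8 T-like cells off therapy had Gzmk at 0.996 (0.923 to 1.07) of PBS and 4.44 (3.16 to 6.43) times 2/week, Ifng at 1.43 (1.33 to 1.54) and 1.75 (1.46 to 2.12) times, and Pdcd1 at 1.41 (1.21 to 1.64) and 0.891 (0.669 to 1.21) times. Klri2 was 3.46 (2.61 to 4.65) times PBS and Spry2, a feedback inhibitor of growth factor signalling, 4.49 (2.49 to 8.65), while Nbea was at 0.217 (0.109 to 0.401), Hspa1a at 0.252 (0.210 to 0.302) and Hspa1b at 0.246 (0.209 to 0.288). Cd160, Epha3 and Ctla2b had 0 UMIs in the 76 cells of 2/week and were at least 7.07-fold, at least 4.96-fold and at least 4.70-fold higher off therapy. Nrg2, which leads cluster T10, and Igfbp4 were 0.193 (0.139 to 0.270) and 0.223 (0.156 to 0.324) of 2/week. Tnfsf4 met the rule only through 1 cell, which held 92.1% of its 2/week UMIs. Cytotoxic effector genes had medians of 0.16 against PBS and 0.85 against 2/week, exhaustion genes 0.22 and 1.02, and interferon response genes -0.10 and 0.69. Cluster T4 held 344 of the 713 off-therapy cells.

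CD4 Tconv-like cells off therapy had Ifng at 0.606 (0.549 to 0.670) of PBS and 2.29 (1.78 to 2.99) times 2/week, Hspa1a at 0.275 (0.251 to 0.301) of PBS, Nrgn at 0.0984 (0.0551 to 0.164) and Elmod1 at 0.207 (0.102 to 0.386). C2cd4b was at 4.77 (2.62 to 9.28) and Penk at 5.91 (4.29 to 8.30) times PBS. Il21, a follicular helper cytokine gene, Sostdc1 and Ifitm1 had 0 UMIs in the 2/week class and were at least 9.07-fold, at least 8.81-fold and at least 6.74-fold higher, with Ifitm1 at log2 2.49 with doublets kept. Il5, Il4 and Il13 were lower than on 2/week. Il5 and Il4 are leading genes of cluster T21, which held 0 off-therapy cells. Il13 is a leading gene of the ILC2-like cluster T8, which held 47 cells off therapy and 412 on 2/week. RNA from such cells in these sums was not told apart. Lyz2, the lysozyme gene of myeloid cells, was 15.5 (7.23 to 39.7) times PBS in CD4 Tconv-like and 13.8 (5.11 to 52.3) times in CD8 T-like cells, in a library whose whole-sample Lyz2 stood at 943 CPM against 35.3. Free pancreas RNA was higher as well, with medians of 1.74 in CD4 Tconv-like cells (led by Ctrb1, 2.51, and Clps, 2.48) and 1.24 in CD8 T-like cells. Under the stricter cell filter the log2 ratio was 1.24 for Penk (against 2.51) and -1.83 for Nrgn (against -3.21). Interferon response genes had medians of -0.07 against PBS and 0.66 against 2/week, beside stress medians of -0.20 and -0.55. In B-like cells the interferon medians were -0.22 and 0.35, the stress medians -0.33 and -0.09, and B cell activation genes were higher than PBS in 18 of 24 members (median 0.33). Cluster A13 held 274 of the 2193 off-therapy B-like cells and 89 of the 2207 of PBS mice. These values thus also follow the mix of the clusters.

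Setting the schedules side by side, the Treg-like share on 2/week was 1.91 (1.57 to 2.32) times that on 1/week at 15 weeks and 3.63 (2.94 to 4.51) times at 30 weeks, and the CD8 T-like share 0.471 (0.395 to 0.561) and 0.372 (0.285 to 0.480) times. ILC2-like cells were at 1.91 (1.63 to 2.25) and 1.30 (1.16 to 1.44) times, closer between the schedules than the Treg-like share only at 30 weeks. NK-like cells were at 1.06 (0.928 to 1.20) and 2.05 (1.79 to 2.34) times. Interferon response genes had medians of -0.76 in Treg-like, -0.54 in CD4 Tconv-like, -0.58 in CD8 T-like and -0.46 in B-like cells on 2/week relative to 1/week at 30 weeks, beside stress medians of 0.25, 0.10, 0.24 and 0.14.

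Macrophage-like cells, phagocytes that clear dying cells, reached the minimum of 50 cells only in the 3 libraries given mIL-2/CD25 at 30 weeks. Tissue-resident and phagocytic macrophage genes were higher off therapy than on 2/week in 22 of 24 members (median log2 ratio 1.15, random lists -0.23 to 0.12), led by the folate receptor gene Folr2 (3.08) and Lyve1 (2.01), and lower on 2/week than on 1/week in 18 of 24 (median -0.67). Inflammatory macrophage genes had medians of 0.01 and -0.05, with Cxcl9 lowest off therapy (-2.01). Interferon response genes had medians of 0.27 and -0.57, the first of which became -0.14 with at least 100 UMIs per member, beside stress medians of 0.15 and 0.01. Free pancreas RNA had medians of 2.17 and -0.75. Cluster A24, led by Apoe and C1qa, held 123 of the off-therapy cells, 35 of those on 2/week and 46 of those on 1/week, and cluster A17, led by Retnla and Fn1, held 96, 115 and 123, so these values also follow the mix of the clusters. The name of A17 is less secure, since its top 10 genes held 1 macrophage and 1 monocyte marker.

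Relative to the untreated 10-week library, PBS mice had Treg-like shares of 1.08 (0.816 to 1.43) times at 15 weeks and 0.806 (0.613 to 1.07) times at 30 weeks, CD8 T-like shares of 1.23 (1.09 to 1.40) and 0.843 (0.740 to 0.962) times, and B-like shares of 1.05 (0.952 to 1.16) and 1.69 (1.54 to 1.85) times. Tnfrsf17, the receptor gene BCMA of plasma cells, was 59.8 (10.5 to 2384) and 46.6 (8.16 to 1862) times its 10-week level over all cells, with 1 UMI at 10 weeks. Chst1 was at 22.8 (8.73 to 84.6) and 14.1 (5.37 to 52.9) times, and Prg2 11.0 (7.83 to 15.9) and 16.1 (11.5 to 23.2) times. C1qa and C1qb were higher too, but 1 cell held 96.6% and 83.5% of their UMIs at 15 weeks. The stromal genes Dcn, Col3a1, Mgp and Col1a2 and the neutrophil gene S100a9 were lower, with 65.9%, 67.9%, 93.5%, 57.6% and 95.8% of the 10-week UMIs in 1 cell. In CD8 T-like cells Ifng was 1.72 (1.58 to 1.87) and 1.23 (1.12 to 1.34) times and Pdcd1 0.871 (0.784 to 0.968) and 0.347 (0.30 to 0.40) times the 10-week level. Inhibitory receptor and exhaustion genes were lower in 19 of 20 members at 30 weeks (median log2 ratio -0.72), where the median of all CD8 T-like genes was itself -0.12. These differences cannot be told apart from the library dates.

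Without clusters, Foxp3 over all retained cells was 40.1 CPM on 2/week, 17.1 on 1/week and 10.5 in PBS mice at 15 weeks, and 14.4, 6.62 and 8.52 at 30 weeks, with 5.06 off therapy and 14.4 at 10 weeks. The ratios to PBS were 3.80 (3.41 to 4.25), 1.62 (1.43 to 1.84), 1.69 (1.48 to 1.93), 0.777 (0.660 to 0.914) and 0.594 (0.507 to 0.696). Whole-sample Gzmk was 0.112 (0.0992 to 0.126) and 0.395 (0.368 to 0.423) of PBS at 15 weeks and 0.0388 (0.0312 to 0.0478) and 0.204 (0.184 to 0.225) at 30 weeks, and Il2ra was 5.35 (5.04 to 5.67), 2.12 (1.98 to 2.27), 7.87 (7.35 to 8.42) and 6.62 (6.18 to 7.1) times. Among droplets thinned to 1500 UMIs with Cd3 and no Cd8 RNA left, 8.06% had a Foxp3 UMI on 2/week at 15 weeks, 3.49% on 1/week and 2.24% in PBS mice. This compares with 0.0905% and 0.208% of B-like cells, which should lack Foxp3, in PBS mice and on 1/week. On 2/week 0 of 680 B-like cells had a Foxp3 UMI, which allows a share of up to 0.541%. Median depths before thinning were 7119 and 6597 UMIs in gated and B-like cells of PBS mice. At 30 weeks the shares were 5.94%, 2.72%, 2.70% in PBS mice and 2.16% off therapy, and 3.55% at 10 weeks, and in B-like cells 0 of 2203 droplets of PBS mice had a Foxp3 UMI, which allows up to 0.167%. Without thinning they were 17.5%, 10.6% and 6.57% at 15 weeks, 10.4%, 4.87%, 5.62% and 5.04% at 30 weeks, and 6.90% at 10 weeks. The thinned ratios to PBS were 3.6 (2.57 to 5.12), 1.56 (1.02 to 2.38), 2.20 (1.58 to 3.10) and 1.01 (0.660 to 1.53) on therapy and 0.80 (0.531 to 1.20) off therapy. With the gate set on full counts before thinning they were 3.08 (2.22 to 4.36), 1.42 (0.942 to 2.15), 2.06 (1.47 to 2.91), 1.05 (0.689 to 1.59) and 0.843 (0.558 to 1.27).

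The genes named in every comparison lie at these positions in the mm10 annotation. On chromosome X lies Foxp3 (ENSMUSG00000039521), from 7573644 to 7595245 on the plus strand. Il2ra (ENSMUSG00000026770) lies on chromosome 2 from 11642807 to 11693193, Cd8a (ENSMUSG00000053977) on chromosome 6 from 71373427 to 71379173 and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892, each on the plus strand. Gzmk (ENSMUSG00000042385) spans 113171608 to 113225908 on the minus strand of chromosome 13. Chromosome 1 carries Ctla4 (ENSMUSG00000026011) from 60887000 to 60915832 on the plus strand, and Ikzf2 (ENSMUSG00000025997) from 69531214 to 69687245 and Pdcd1 (ENSMUSG00000026285) from 94038305 to 94052553 on the minus strand. UMIs were counted over whole genes, so no value belongs to a single exon.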

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

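No test was chosen for this part, before or after the results were seen. In B-like cells a pair of results went one way at 15 weeks and the other at 30 weeks. The B-like share on 1/week was 1.10 (1.01 to 1.20) times that of PBS mice at 15 weeks and 0.553 (0.511 to 0.598) times at 30 weeks. The dissociation and stress list in B-like cells on 2/week had a median log2 ratio to PBS of 0.15 at 15 weeks and -0.41 at 30 weeks. The difference was not tested in either case, because each group has 1 library and the ages were made on different dates.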

How the results depend on the processing

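Omission of each gene's top cell, the counting of cluster T12 as CD4 Tconv-like and the droplet gate set before thinning were chosen only after the results were seen. No paired analysis was possible because each group has 1 library. Among values that answer a comparison, 2388 alternatives stayed within the interval of counting error or, for list medians, the width of the random lists, 76 moved beyond it, in part with another sign, and 5 turned a direction that had been outside the range of no change. Among single genes these counts were 1769, 169 and 18. The ratios of the Treg-like, CD8 T-like, ILC2-like, NK-like, CD4 Tconv-like and B-like shares stayed within their intervals in all 7 alternative clusterings. Without thinning, the droplet gate gave Treg ratios to PBS at 30 weeks of 1.85 on 2/week (from 5.44) and 0.867 on 1/week (from 1.5). Its ratio off v 2/week was 0.483 (from 0.20). Thinned to 1500 UMIs these ratios were 2.20, 1.01 and 0.363, so the turn on 1/week was not seen there. The move is in part by construction, because the gate takes in NK-like, ILC2-like and gamma-delta T-like cells. The rest of that move was not tested. Alternatives of the classes could give no value for whole-sample levels, and the gate none for CD8 T-like cells. Depth limits classes of few cells, such as the 66 ILC2-like cells of PBS mice and the 76 CD8 T-like cells on 2/week at 30 weeks, and macrophage-like cells, compared only among the 3 libraries given mIL-2/CD25 at 30 weeks. The cause was not tested in any of the changes listed next, unless stated, and all are log2 unless a fold is named.

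As a mean over cells of each cell's own CPM, in which shallow cells weigh as much as deep ones by construction, the whole-sample folds were Foxp3 2/week at 30 weeks 2.25 (from 1.69), 1/week at 30 weeks 0.958 (from 0.777) and off therapy 0.700 (from 0.594), Ctla4 2/week at 15 weeks 0.988 (from 1.06) and off therapy 1.00 (from 0.815), Ifng off therapy 1.02 (from 0.812), Pdcd1 2/week at 30 weeks 1.15 (from 0.805), 1/week at 30 weeks 1.07 (from 0.849) and off therapy 1.08 (from 0.811), Lyz2 1/week at 15 weeks 0.962 (from 1.16), C1qa 2/week at 15 weeks 1.24 (from 0.557). Without each gene's top cell the log2 ratio turned for Dach2 in Treg-like cells 1/week at 15 weeks -0.57 (from 4.27), Csf2 in CD4 Tconv-like cells 2/week at 15 weeks 0.63 (from -2.40), Csf2 in CD4 Tconv-like cells 1/week at 15 weeks 0.58 (from -2.11), Ccl1 in CD4 Tconv-like cells 2/week at 15 weeks 0.56 (from -3.67), Ccl1 in CD4 Tconv-like cells 1/week at 15 weeks 0.65 (from -2.02) and Tnfsf4 in CD8 T-like cells off v 2/week 0.88 (from -2.12). Under the stricter cell filter the log2 ratio turned for Tnfrsf4 in CD8 T-like cells 2/week at 15 weeks -0.32 (from 1.70), Spp1 in CD8 T-like cells 2/week at 15 weeks 0.43 (from -3.32) and Tnfsf4 in CD8 T-like cells off v 2/week 3.76 (from -2.12). With resolution 1.5 the log2 ratio turned for Ctla4 in Treg-like cells 1/week at 15 weeks -0.0295 (from 0.13).

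With doublets kept the medians in Treg-like cells were Treg identity off therapy -0.25 (from -0.45), naive off therapy 0.10 (from 0.25), cytotoxic 2/week at 15 weeks -0.29 (from 0.12). In CD4 Tconv-like cells they were cytotoxic 1/week at 15 weeks -0.52 (from -0.27) and off v 2/week 0.17 (from 0.49), exhaustion off therapy -0.34 (from -0.25), T helper 2/week at 15 weeks -0.82 (from -0.59), proliferation 2/week at 15 weeks -1.07 (from -0.79). In macrophage-like cells they were antigen presentation off v 2/week 0.0167 (from 0.23), resident macrophage 2/week v 1/week -0.88 (from -0.67), proliferation off v 2/week -0.47 (from 0.02) and 2/week v 1/week 0.76 (from 0.09). Under the stricter cell filter the medians in CD8 T-like cells were naive 1/week at 30 weeks 0.61 (from 0.37), exhaustion 2/week at 15 weeks -0.97 (from -0.59) and 1/week at 30 weeks -0.39 (from -0.04), T helper 2/week at 15 weeks -0.33 (from -0.05), proliferation 2/week at 30 weeks -0.29 (from 0.15), free pancreas RNA off therapy 0.75 (from 1.24). In Treg-like cells they were cytotoxic 1/week at 15 weeks 0.52 (from 0.25). In CD4 Tconv-like cells they were cytotoxic 1/week at 30 weeks -0.27 (from -0.57) and off therapy -0.26 (from -0.39) and off v 2/week 0.81 (from 0.49), exhaustion 1/week at 15 weeks -0.11 (from 0.05) and 1/week at 30 weeks 0.26 (from -0.16) and off v 2/week 0.64 (from 0.31), T helper 1/week at 15 weeks -0.11 (from -0.23) and off v 2/week 0.29 (from -0.01), proliferation 2/week at 15 weeks -1.24 (from -0.79). With resolution 1.5 the medians in Treg-like cells were Treg identity 2/week at 15 weeks 0.43 (from 0.14) and 1/week at 15 weeks 0.0907 (from 0.33), cytotoxic 2/week at 15 weeks -0.56 (from 0.12) and 1/week at 30 weeks -0.23 (from -1.19) and off therapy -0.19 (from -0.48) and off v 2/week 0.35 (from -0.02), anergy 1/week at 15 weeks -0.0492 (from 0.18), antigen presentation 2/week at 15 weeks -0.39 (from -0.05). In CD4 Tconv-like cells they were free pancreas RNA 2/week at 15 weeks -2.09 (from -1.35). With at least 100 UMIs per member the medians in Treg-like cells were IL-2 and STAT5 off therapy -0.33 (from -0.19), cytotoxic 1/week at 30 weeks -1.60 (from -1.19) and off therapy -0.98 (from -0.48), exhaustion off v 2/week -0.22 (from 0.11), T helper 1/week at 30 weeks -0.19 (from 0.36) and off therapy -0.21 (from -0.02) and off v 2/week -0.41 (from 0.11), residency 2/week at 30 weeks 0.0293 (from -0.74) and off therapy 0.29 (from -0.25). In CD4 Tconv-like cells they were cytotoxic 1/week at 15 weeks -0.57 (from -0.27), exhaustion 2/week at 15 weeks -0.63 (from -0.42), anergy 2/week at 15 weeks 0.0818 (from -0.11), T helper off v 2/week 0.40 (from -0.01), proliferation 2/week at 15 weeks -0.49 (from -0.79). In macrophage-like cells they were interferon off v 2/week -0.14 (from 0.27) and 2/week v 1/week -0.36 (from -0.57), resident macrophage 2/week v 1/week -0.86 (from -0.67). In CD8 T-like cells they were proliferation 2/week at 15 weeks -0.35 (from -0.97) and off therapy 0.0474 (from 0.24). In B-like cells they were proliferation 1/week at 15 weeks 0.19 (from -0.01). Without each gene's top cell the medians in CD4 Tconv-like cells were cytotoxic 2/week at 30 weeks -1.09 (from -0.76) and 1/week at 30 weeks -0.80 (from -0.57) and off v 2/week 0.70 (from 0.49), exhaustion 2/week at 30 weeks -1.07 (from -0.78) and off v 2/week 0.59 (from 0.31), T helper off v 2/week 0.27 (from -0.01), antigen presentation off v 2/week 0.68 (from 0.46). In CD8 T-like cells they were exhaustion 2/week at 30 weeks -1.26 (from -0.81) and off v 2/week 1.39 (from 1.02), interferon 2/week at 15 weeks -0.41 (from -0.26), free pancreas RNA 1/week at 15 weeks -2.43 (from -1.80). In Treg-like cells they were T helper off v 2/week -0.42 (from 0.11), proliferation 2/week at 15 weeks -0.36 (from -0.77). In B-like cells they were interferon 2/week at 15 weeks -0.82 (from -0.68). In macrophage-like cells they were interferon 2/week v 1/week -0.73 (from -0.57), proliferation off v 2/week 0.45 (from 0.02). With a prior of 0.5 UMIs the medians in CD8 T-like cells were free pancreas RNA off v 2/week 4.54 (from 2.71). With a prior of 5 UMIs the medians in CD8 T-like cells were free pancreas RNA off v 2/week 1.69 (from 2.71).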

Other observations

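All the tests reported in this part, and the genes it names, were chosen only after the results were seen. Cluster T13, a gamma-delta T-like cluster led by Cd163l1, Il1r1 and Il23r, genes of cells that make interleukin-17, was 4.84% of retained cells on 2/week at 30 weeks and 2.66% on 1/week against 0.837% in PBS mice, ratios of 5.78 (4.18 to 8.16) and 3.18 (2.22 to 4.62). At 15 weeks its ratios were 2.02 (1.36 to 3.03) and 1.71 (1.12 to 2.63), and off therapy 1.02 (0.669 to 1.56). Cluster T14, unnamed and led by Rcbtb2, Zbtb16 and Il12rb2, was 1.98% on 2/week and 1.18% on 1/week at 15 weeks against 0.414% in PBS mice, and 5.23%, 1.14% and 0.409% at 30 weeks. Zbtb16 encodes PLZF, a transcription factor of innate-like T cells and innate lymphoid precursors. The unnamed CD4+ cluster T12, led by Il10, Lag3 and Il21, went the other way, with ratios to PBS of 0.363 (0.256 to 0.505) and 0.672 (0.506 to 0.887) at 15 weeks, 0.0763 (0.0300 to 0.163) and 0.424 (0.278 to 0.632) at 30 weeks and 0.765 (0.573 to 1.02) off therapy. Counted as CD4 Tconv-like, it lowered the Treg-like share to 39.1% on 2/week and 11.8% in PBS mice at 15 weeks, and to 54.4% and 9.41% at 30 weeks.

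Cluster A32, unnamed and led by Ccl6, F5, Ccr3 and Alox15, the last pair being genes of eosinophils, held 7 and 11 cells on 2/week and 1/week at 15 weeks and 10 and 55 at 30 weeks, and 0 in the 10-week, PBS and off-therapy libraries. A count of 0 allows a share of up to 0.0849% and 0.0686% in the PBS libraries, and the median depth of the cluster was 786 UMIs. In NK-like cells at 15 weeks Nek6, a mitotic kinase gene, was 5.40 (2.33 to 15.4) and 3.93 (1.63 to 11.4) times PBS on 2/week and 1/week. Cluster T6 held 59 of the 296 NK-like cells of PBS mice, 346 of 508 on 2/week and 92 of 432 on 1/week. The 2/week value thus also follows the mix of the clusters. At 30 weeks NK-like cells had Gzmk at 0.0662 (0.0289 to 0.134) and 0.346 (0.210 to 0.558) of PBS, Serpinb9b, a granzyme inhibitor gene, at 0.152 (0.114 to 0.201) and 0.369 (0.286 to 0.474), and Fgd5 at least 9.12-fold and at least 5.76-fold higher from 0 UMIs in PBS. The NK-like class was made up of different clusters, with T5, led by Gzma and with Serpinb9b in its top 10 genes, at 163 of 227 cells in PBS mice and 112 of 765 on 2/week, where T6 held 586, so these levels also follow that mix. In ILC2-like cells at 30 weeks Irf4, a transcription factor gene of activated lymphocytes, was at least 4.39-fold and at least 15.7-fold higher from 0 PBS UMIs, Baiap2 at least 3.97 and at least 4.24 times PBS, and the interferon-induced Isg15 0.227 (0.159 to 0.328) and 0.233 (0.161 to 0.341) of PBS. Cluster T7 held 53 of the 66 ILC2-like cells of PBS mice and T8, led by Csf2 and Il13, 9, while T8 held 412 of 860 on 2/week and 392 of 563 on 1/week, so these values follow the mix as well. At 15 weeks the cell cycle gene Smc2 was 0.354 (0.228 to 0.560) and 0.372 (0.214 to 0.640) of PBS in ILC2-like cells, and Vegfc at least 3.05-fold and at least 4.11-fold higher. At that age T8 held 14 of the 81 ILC2-like cells of PBS mice, 199 of 472 on 2/week and 70 of 222 on 1/week. The 15-week values thus also follow the mix. Whole-sample Il13, a type 2 cytokine gene, was 73.1 (39.5 to 153) and 209 (114 to 438) times PBS at 30 weeks.

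ILC2-like cells were a higher share of retained cells in all 4 libraries on therapy, at 6.69 (5.27 to 8.58), 3.50 (2.70 to 4.57), 15.3 (11.9 to 20.0) and 11.8 (9.16 to 15.5) times PBS. A loss of other cells would raise the remaining classes alike, but cluster T1, led by Klra6, Trdc and Cd160, had upper bounds of at most 1.76 times PBS in these libraries. That argues against such a loss only if T1 cells were not lost as well, which shares without cell numbers cannot show. Against the clustering as the source, the 13 ILC2 markers summed over all cells without clusters were 2.69, 1.5, 4.00 and 4.07 times PBS with a lowest lower bound of 1.47, although cluster T21 and Treg-like cells also express some of these markers. PBS libraries poor in these cells by themselves are argued against as the whole cause, since the 4 libraries off drug held 1.86% and 1.23% (PBS), 2.42% (10 weeks) and 2.67% (off therapy), with upper bounds of at most 3.11%, below the lowest lower bound on therapy of 5.72%. Only the libraries at 30 weeks shared a date with the off-therapy library. A loss that included T1 cells stays open, and each group is 1 library of 3 mice. An increase with mIL-2/CD25, whose target CD25 ILC2 carry, is a hypothesis that 1 library per group leaves untested.

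Clusters A17 and A24, led by Retnla and Fn1 and by Apoe and C1qa, together held 3.29% of retained cells on 2/week, 4.36% on 1/week and 3.66% off therapy at 30 weeks against 0.353% in PBS mice, ratios of 9.30 (5.75 to 15.9), 12.3 (7.67 to 21.0) and 10.4 (6.48 to 17.5). At 15 weeks they were 0.423%, 0.529% and, in PBS mice, 0.598%. Exocrine tissue carried over with the islets could bring such cells. The 10 acinar genes, summed without the 2 top cells of each library, were 2.12 and 2.95 times PBS on 2/week and 1/week, well below the ratios of the cells. That argues against carry-over as the whole cause there, if such cells and acinar RNA rise in proportion, which was not tested. Off therapy the same sum was 10.8 times PBS, as carry-over would need, so that library stays open. Treatment, the PBS library and the pooled mice were not told apart by any test.

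On 2/week the interferon response list was lower than in PBS mice in Treg-like, CD4 Tconv-like, CD8 T-like and B-like cells at both ages. A shift of cells between clusters could lower it within a class, but within CD4 Tconv-like, CD8 T-like and B-like clusters the list was below its random range in 8 of 8 clusters at 15 weeks and 5 of 5 at 30 weeks, with a highest median of -0.28, although no CD8 T-like cluster had 50 cells on 2/week at 30 weeks. Treg-like cells are 1 cluster, so there a shift was not tested. On 1/week it was below in 7 of 8 and 6 of 9, and in T0 at 30 weeks it was above its range (median 0.35, range up to 0.33). More dissociation stress is argued against only for the difference from PBS in B-like cells at 30 weeks, where the stress median was -0.41. Off therapy the B-like stress median was below PBS too, so that value rests on 1 PBS library. Relative to 1/week, B-like cells on 2/week had a lower interferon median beside a higher stress median. Dissociation stress thus stays open there and in the other classes, with stress medians of up to 0.64 in Treg-like cells at 15 weeks. A PBS library high in interferon response genes by itself is argued against as the whole cause at 30 weeks, since the off-therapy library was above 2/week in the 4 classes (lowest median 0.35). At 15 weeks it cannot be told apart, since 2/week was below 1/week in Treg-like, CD4 Tconv-like and B-like cells (medians -0.52, -0.39 and -0.37) but not in CD8 T-like cells (0.0237). Less interferon signalling in treated islets is a hypothesis, and chance differences between pools of 3 mice remain open and untested.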
